A study of Mus musculus with 22 samples.

How the data were processed

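RNA of 22 samples of mouse subcutaneous connective tissue, extracted with Tri-Reagent, was measured on arrays after labelling as biotin cRNA. Per the labels the authors processed the arrays with RMA and the affy package, for which no versions are stated. RMA corrects background, normalizes quantiles and summarises the probes of a set, and the deposited values were on the log2 scale, as their range of 1.89 to 14.4 shows. In vivo and ex vivo arrays followed different distributions, with a median of sample medians of 7.32 and 6.88, so the settings looked normalized separately. No pair of samples held identical values.

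Samples were grouped by their titles into in vivo shortened and stretched tissue (7 animals) and ex vivo shortened and stretched tissue (4 animals). Samples with the same number in a setting were taken as 1 animal, since the series design states a comparison within animals. Deviations from the group mean correlated between the samples of an animal with r of 0.385 to 0.867 in vivo, highest with the animal's own number for 5 of 7, and 0.109 to 0.284 ex vivo, highest for 2 of 4. Pearson correlations between samples of a group were 0.967 to 0.994 in vivo shortened, 0.953 to 0.995 in vivo stretched, 0.991 to 0.995 ex vivo shortened and 0.977 to 0.991 ex vivo stretched. The number of arrays limits the precision.

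Of 22690 probes 64 control probes were left out and 22626 tested. A total of 20380 probes carried 1 gene symbol, 691 several and 1555 none. For results per gene the probe with the highest mean over all samples was used, among those with 1 symbol, which gave 12393 genes, 4956 of them with several probes. Symbols followed the supplied table of probes and genes, with older and newer names matched, and 29 symbols without a match were kept as written.

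Each of 4 comparisons was fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Stretched minus shortened tissue was fitted within each setting with the animal as a block. The difference of the stretch effect was fitted on all 22 samples with 11 animal blocks and a stretch effect per setting. Shortened tissue was compared between settings with no block, since the animals differ. Changes in that comparison are given relative to the median change of all probes.

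Gene lists, 14 of pathways and 12 of cell types, held 561 genes, of which 506 were measured and 0 stood in several lists. Each list was tested with camera at a preset correlation of 0.01 between genes, adjusted over the 26 lists of a comparison. The lists of sarcomere and of calcium and energy genes also served as markers of skeletal muscle. Camera was repeated with an estimated correlation, fry tested whether the genes of a list moved on balance in 1 direction, and exact sign flips over animals, two-sided, tested list means. Where the calls are counted over a list alone, the adjustment covers its members only.

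The agreement of the settings was measured as Pearson and Spearman correlation across genes, with p from exact flips of the ex vivo pairs. RNA quality was measured as the difference between 3' and 5' control probes of Actb and Gapdh, compared with exact two-sided sign flips. The first principal component held 53.6% of the variance in vivo and 35.0% ex vivo. In vivo animals 1 to 3 and 4 to 7 formed sets of low and high Gapdh difference, and results are given within these sets.

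Named genes were chosen by a fixed rule. It takes the 10 largest changes in each direction among genes past the threshold, for comparisons within animals only if every pair changed the same way. Where fewer than 5 passed in a direction, genes with the smallest p filled the list to 5 and are given as values. It adds 2 to 4 members of each list with the smallest p, and Acta1, Myh4, Myod1, Acta2, Tgfb1 and Col1a1 in both stretch comparisons. The 4 comparisons with their tests, the 26 gene lists, the groups and this rule were set before the data were examined.

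Alternatives changed 1 choice at a time: quantile normalization, centring on medians, brighter probes only, probes with a mean of at least 6, no mean-variance trend, robust eBayes, array weights, thresholds of 0.10 or a 1.5-fold change, 1 value per gene, no animal block, all samples in 1 fit, stretched instead of shortened tissue, each animal left out, and for the agreement brighter genes only or no muscle lists. Added after seeing the data were muscle content as a covariate (the mean of the 2 muscle lists per sample) and leaving out the muscle-rich pairs (in vivo animals 5 and 6, ex vivo animals 3 and 4). Muscle-rich here means the pairs of each setting whose pieces differed most in muscle content. In vivo animals 3, 4 and 7 stayed in, though muscle content in their pieces was high too (7.38 to 9.62). Exact sign flips of list means, RNA quality as a covariate or by set, and quantile normalization of all 22 samples were added then as well. Also chosen then were an estimated correlation within these added fits, covariates given to the wrong animals, the range of muscle content in shortened tissue, a list of genes of body position with random lists of matched expression, and changes between settings relative to the median shift. The shared sign of the 2 settings had been planned for called genes and is given for all genes, since limma called none in either setting.

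The procedure was tested on simulated data of the same design, with noise drawn independently for each probe. A change of 1 on the log2 scale was recovered for 92.5% of probes in vivo, 64.2% ex vivo, 83.6% for the difference and 83.6% between settings. For a change of 0.5 these shares were 80.6%, 22.4%, 32.8% and 55.2%. Lists shifted by 0.5 were recovered in 3 of 3 cases in each comparison, except 2 of 3 ex vivo with an estimated correlation. With the preset correlation 1 unshifted list was called in vivo. Genes in the data move together, so these simulations do not measure false list calls at the preset correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.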

Results

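Gene expression was measured with arrays of biotin-labelled cRNA in loose connective tissue under the skin of the trunk of male C57BL/6 mice weighing 19 to 24 g. Each animal gave a stretched and a shortened piece of tissue, assigned at random. The 22 samples came from 11 animals, 7 with tissue held in vivo and 4 with tissue held ex vivo, so the replicates were animals. The labels give neither the force nor the duration of the stretch. Values were log2 signals of 22626 probes, which stand for 12393 genes. The median signal of a sample lay between 7.29 and 7.42 in vivo and between 6.85 and 6.90 ex vivo. The number of arrays limits the precision of every value. Errors of single genes are standard errors (SE) of the limma fit, with n = 7 animals in vivo and n = 4 ex vivo.

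The in vivo comparison asked how gene expression in stretched tissue differed from that in shortened tissue of the same animal, with muscle-related genes as the study's theme. Genes of the striated muscle sarcomere, the contractile unit of muscle fibres, were on average higher in stretched tissue. Of 31 measured sarcomere genes 24 were higher, with a median log2 difference of 1.49 and a mean of 1.22 ± 1.47 (SD of 7 pairs). The fast myosin heavy chain Myh4 differed by 2.76 ± 0.71 and was higher in 7 of 7 animals. Its mean signal was 7.95 ± 3.90 (SD, n = 7) in shortened and 10.70 ± 3.63 (SD, n = 7) in stretched tissue. Skeletal alpha-actin, Acta1, differed by 2.22 ± 0.60 and was higher in 6 of 7 animals. The fast troponin C gene Tnnc2 differed by 2.56 ± 0.73, and Myoz1, which encodes a protein of the Z-disc, by 1.82 ± 0.48. The sarcomere list was called by camera with adjusted p = 9.22e-08, against adjusted p = 0.446 with an estimated correlation. No member passed over all genes tested, and 20 passed adjusted over the list alone.

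The size of the sarcomere difference varied between animals. Differences of the list mean in animals 1 to 7 were -0.03, 0.42, 1.46, -0.55, 3.80, 2.18 and 1.28, so the list was higher in 5 of 7. An exact sign-flip test of the sarcomere list mean, two-sided, gave p = 0.0938, where 7 pairs allow no p below 0.0156. Shortened tissue alone ranged from 4.81 to 9.23 in the sarcomere list mean (6.35 ± 1.74, SD, n = 7). Stretched tissue averaged 7.57 ± 1.87 (SD, n = 7). The same list serves as a marker of skeletal muscle, which lies next to this tissue as the panniculus carnosus.

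**Figure D1:**
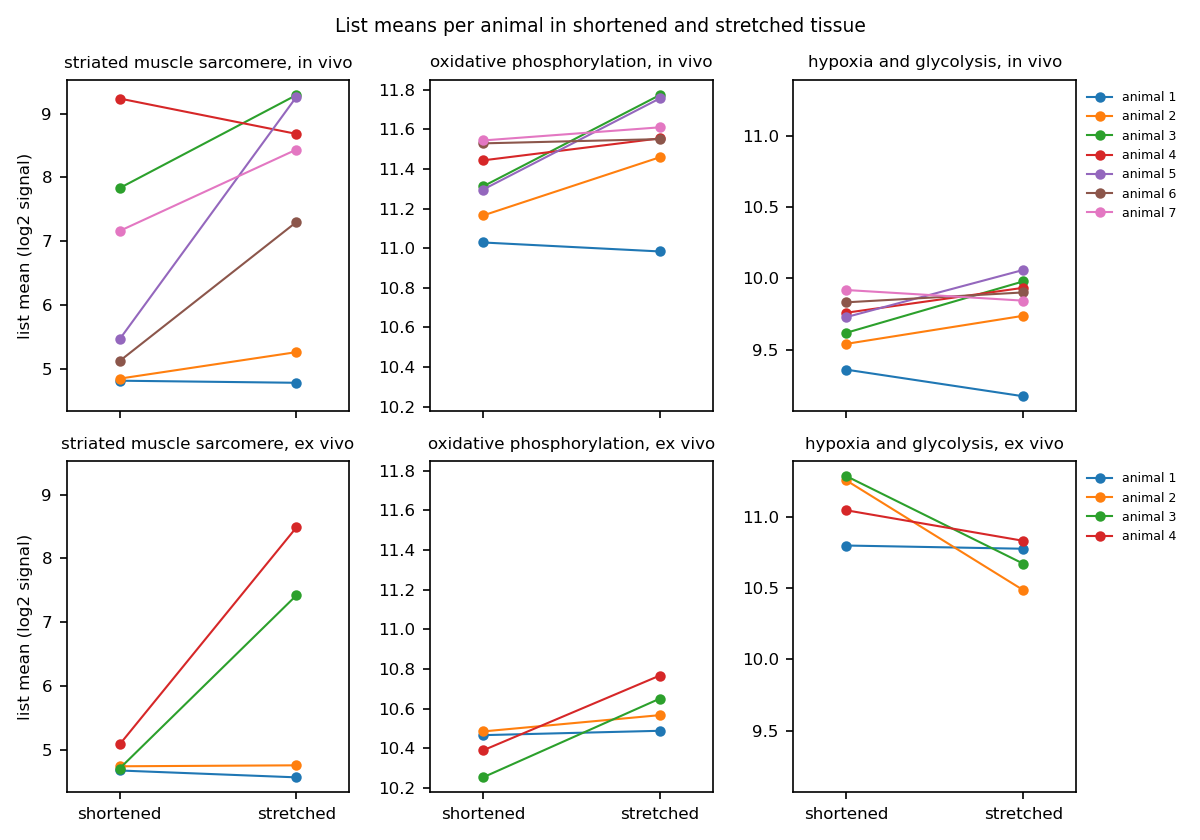
Mean log2 signal of the sarcomere, oxidative phosphorylation and hypoxia and glycolysis lists in shortened and stretched tissue, with 1 line per animal (7 in vivo in the top row, 4 ex vivo in the bottom row). The sarcomere mean spans 4.81 to 9.23 in shortened in vivo tissue and 4.68 to 5.08 in shortened ex vivo tissue, and the hypoxia and glycolysis mean is lower after stretch in 4 of 4 ex vivo animals.

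Genes for calcium handling and energy supply of muscle were higher too. Of 22 members 21 were higher, and the list mean in 6 of 7 animals, with a median of 1.36 (adjusted p = 2.27e-11, and adjusted p = 0.446 with an estimated correlation). None passed over all genes tested and 20 passed adjusted over the list alone. Examples are the calcium pump Atp2a1 (2.11 ± 0.64), its inhibitor sarcolipin, Sln (2.21 ± 0.55), the calcium buffer parvalbumin, Pvalb (2.21 ± 0.62), and the phosphorylase kinase subunit Phkg1 (0.84 ± 0.19). Myogenic regulators were higher by a median of 0.07, with 16 of 21 members higher and the list mean in 4 of 7 animals (adjusted p = 0.0139, and adjusted p = 0.480 with an estimated correlation). No myogenic member passed over all genes or adjusted over the list alone, and the call ended without animal 5 (0.0596) or 7 (0.0962). Among them Myf6, a muscle transcription factor abundant in mature fibres, differed by 1.22 ± 0.38, and the acetylcholine receptor subunit Chrnb1 by 0.56 ± 0.17. Myod1, which commits cells to the muscle lineage, differed by 0.40 ± 0.14 and was higher in 6 of 7 animals. Its adjusted p was 0.188. Smooth muscle and myofibroblast genes had a median of 0.16, with 13 of 19 higher, the list mean in 6 of 7 animals, and none passing over all genes or adjusted over the list alone (adjusted p = 0.0366, and adjusted p = 0.494 with an estimated correlation). Their lowest p values belonged to desmin, Des (1.16 ± 0.34), and the tropomyosins Tpm2 (1.00 ± 0.34) and Tpm1 (1.33 ± 0.46), genes that skeletal muscle also expresses. The call of the list smooth muscle and myofibroblast contractile ended without any 1 of animals 3 to 6 (adjusted p from 0.0600 to 0.0941), without animals 5 and 6 together (0.214) and in the low Gapdh set of RNA quality (0.381). Smooth muscle actin, Acta2, the marker of myofibroblasts, differed by 0.16 ± 0.19 with adjusted p = 0.698.

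Oxidative phosphorylation genes, which run mitochondrial respiration, were higher in 31 of 31 members in vivo. Their median was 0.20 (adjusted p = 9.29e-14, and adjusted p = 0.446 with an estimated correlation), and the list mean was higher in 6 of 7 animals. Of its members 0 passed over all genes tested and 23 adjusted over the list alone, among them the ATP synthase subunit Atp5b (0.21 ± 0.05) and the citric acid cycle enzymes Idh3a (0.43 ± 0.12) and Mdh2 (0.24 ± 0.07). With the muscle content of each sample as a covariate the median of oxidative phosphorylation was 0.09 (adjusted p = 0.000189). At an estimated correlation that fit called 0 lists (smallest adjusted p 0.734). Adipocyte genes were higher in 16 of 16 members and the list mean in 6 of 7 animals, with a median of 0.49 (adjusted p = 2.51e-06, and adjusted p = 0.446 with an estimated correlation). No adipocyte gene passed over all genes or adjusted over the list alone, and the lowest p values were those of the adipocyte transcription factor Cebpa (0.49 ± 0.13) and hormone-sensitive lipase, Lipe (0.66 ± 0.19).

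Markers of vessels were also higher in stretched tissue in vivo. All 7 pericyte genes were higher, and the list mean in 5 of 7 animals, with a median of 0.43 (adjusted p = 0.000359, and adjusted p = 0.446 with an estimated correlation). The subunits of a potassium channel of pericytes, Abcc9 (0.59 ± 0.13) and Kcnj8 (0.47 ± 0.12), were the 2 members that passed adjusted over the list alone, and none passed over all genes tested. Endothelial genes had a median of 0.32, with 14 of 17 higher and the list mean in 5 of 7 animals (adjusted p = 0.00815, and adjusted p = 0.446 with an estimated correlation). Within the endothelial list, Emcn (0.38 ± 0.15) and the VEGF receptor Kdr (0.48 ± 0.21) were higher. The 2 endothelial members that passed adjusted over the list alone went the other way, the lymphatic hyaluronan receptor Lyve1 (-0.28 ± 0.06) and the angiopoietin receptor Tek (-0.32 ± 0.07). None passed over all genes, and the call ended without animal 6 (adjusted p = 0.0504) and without animals 5 and 6 (0.0929).

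Lists of fibroblasts, matrix, macrophages and nerve were lower in stretched tissue in vivo. Fibroblast genes were lower in 17 of 19 members and in 7 of 7 animals, with a median of -0.15 (adjusted p = 0.000231, and adjusted p = 0.446 with an estimated correlation). Exact sign flips of the fibroblast mean, two-sided, gave p = 0.0156 (adjusted p = 0.203). None passed over all genes tested and 10 passed adjusted over the list alone. They include Pi16 (-0.42 ± 0.10) and Dpp4 (-0.38 ± 0.10), both markers of fascia and adventitial fibroblasts, the microfibril gene Mfap5 (-0.30 ± 0.07) and the surface protease gene Fap (-0.21 ± 0.05). Genes of collagens and elastic matrix were lower in 23 of 30 members and the list mean in 5 of 7 animals, with a median of -0.09 (adjusted p = 0.00483, and adjusted p = 0.446 with an estimated correlation). Over all genes none of these passed and 3 did so adjusted over the list alone, and the call ended without animal 1 (0.0730) and in the high Gapdh set (0.116). Col5a1 (-0.13 ± 0.03), the elastic fibre genes Fbln5 (-0.22 ± 0.06) and Eln (-0.25 ± 0.07), and the proteoglycan gene Vcan (-0.23 ± 0.07) had its lowest p values. Col1a1, the main fibrillar collagen gene, differed by -0.12 ± 0.05, with adjusted p = 0.194. Macrophage genes were lower in 18 of 18 members and the list mean in 5 of 7 animals, with a median of -0.15 (adjusted p = 7.98e-06, and adjusted p = 0.446 with an estimated correlation). Adjusted over the list alone 3 of them passed and over all genes none, with Itgam (-0.34 ± 0.10), Cd68 (-0.27 ± 0.08) and Fcer1g (-0.21 ± 0.06) lowest in p. Schwann cell and nerve genes were lower in 9 of 9 members and the list mean in 6 of 7 animals, with a median of -0.35 (adjusted p = 5.46e-05, and adjusted p = 0.446 with an estimated correlation). Of these none passed over all genes and 8 passed adjusted over the list alone, among them the Schwann cell transcription factor Sox10 (-0.46 ± 0.14) and the myelin genes Pmp22 (-0.25 ± 0.07) and Mal (-0.54 ± 0.18). Muscle content as a covariate in the fit of all samples made 3 of these medians much smaller. They were -0.06 for fibroblast, -0.02 for collagen and -0.04 for macrophage genes, while that of Schwann cell and nerve genes was -0.33. In the fit of the in vivo samples alone they shrank less, to -0.11, -0.05, -0.10 and -0.28 in the same order. At the preset correlation camera there still called fibroblast (adjusted p = 0.00293), macrophage (0.00327) and Schwann cell genes (0.000237), but not collagen genes (0.0605). At an estimated correlation it called 0 lists.

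The other 14 lists were not called in vivo, with medians from -0.06 to 0.10 and a smallest adjusted p of 0.0515. They hold the immediate early genes, the SRF and YAP/TAZ targets and the TGF-beta pathway, all linked to mechanical load. The mean of the TGF-beta pathway list was lower in 7 of 7 animals by a small amount, -0.03 on average (exact two-sided sign-flip p = 0.0156, the smallest 7 pairs allow, adjusted p = 0.203 over 26 lists). Tgfb1 differed by -0.03 ± 0.09. The median and the mean of the lymphocyte list differed in sign (0.05 and -0.00). Hypoxia and glycolysis genes went both ways, and 16 of 23 passed adjusted over the list alone, 11 higher and 5 lower. Hexokinase 2, Hk2 (0.60 ± 0.15), and lactate dehydrogenase A, Ldha (0.36 ± 0.10), were higher, and the collagen prolyl hydroxylase subunit P4ha1 (-0.26 ± 0.06) and Mxi1 (-0.17 ± 0.04) were lower. The calprotectin genes of neutrophils, S100a8 (0.52 ± 0.10) and S100a9 (0.59 ± 0.15), were higher in a list that was not called.

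As none passed in vivo, the genes of smallest p outside the lists are given as values, with Krtdap of the uncalled keratinocyte list. They differed in the same direction in 7 of 7 animals. Higher in stretched tissue were Prtn3 (0.84 ± 0.16), a serine protease of neutrophils, Tst (0.57 ± 0.11), Pax1 (0.43 ± 0.09), a transcription factor of the developing axial skeleton, and Fbxo31 (0.24 ± 0.04), each with adjusted p = 0.172. Lower were Zic1 (-1.95 ± 0.27), a zinc finger transcription factor, Slc4a10 (-1.44 ± 0.22), a bicarbonate transporter, Krtdap (-1.27 ± 0.17), a keratinocyte gene, Ccn3 (-0.53 ± 0.08), a matrix-associated signalling protein, and Akr1b8 (-0.32 ± 0.04), each with adjusted p = 0.153.

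In the limma test over all 22626 probes, 0 probes were called in vivo, and 4373 had an unadjusted p under 0.05, of which 1799 were higher and 2574 lower, where 1131.3 are expected by chance. That count was 1097 with muscle content as a covariate, 1080 without the animal block, 2582 without animal 3, 2777 without animal 5 and 2875 without animals 5 and 6, whose stretched samples held the most added muscle signal. Of the 26 lists camera called 12, fry called 0 and exact sign flips called 0 (smallest adjusted p 0.203). The muscle covariate, which is made of the 2 skeletal muscle lists themselves, ended the calls of sarcomere, calcium and energy, myogenic, smooth muscle, collagen and endothelial lists, and in the fit of all samples also that of macrophages (adjusted p = 0.217). It gained calls of inflammatory cytokines (adjusted p = 0.0318, 22 of 29 higher) and lymphocyte genes (0.0347), and in the fit of all samples of lymphocyte (0.00344) and neutrophil genes (0.0115), all higher. With an estimated correlation the covariate left 0 lists called in either fit (smallest adjusted p 0.734 and 0.514). RNA quality split the animals, with a difference between 3' and 5' Gapdh control probes of 0.111 to 0.272 in animals 1 to 3 and 0.866 to 3.61 in animals 4 to 7. Within these sets 0 probes were called in either, with 1981 and 2157 at an unadjusted p under 0.05, and the list striated muscle sarcomere was called in both at the preset correlation (adjusted p = 1.80e-06 and 1.12e-11) and in neither with an estimated correlation (0.638 and 0.631). The Gapdh difference was, stretched minus shortened, -0.22 ± 0.98 (SD, n = 7, exact two-sided p = 0.656).

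**Figure D2:**
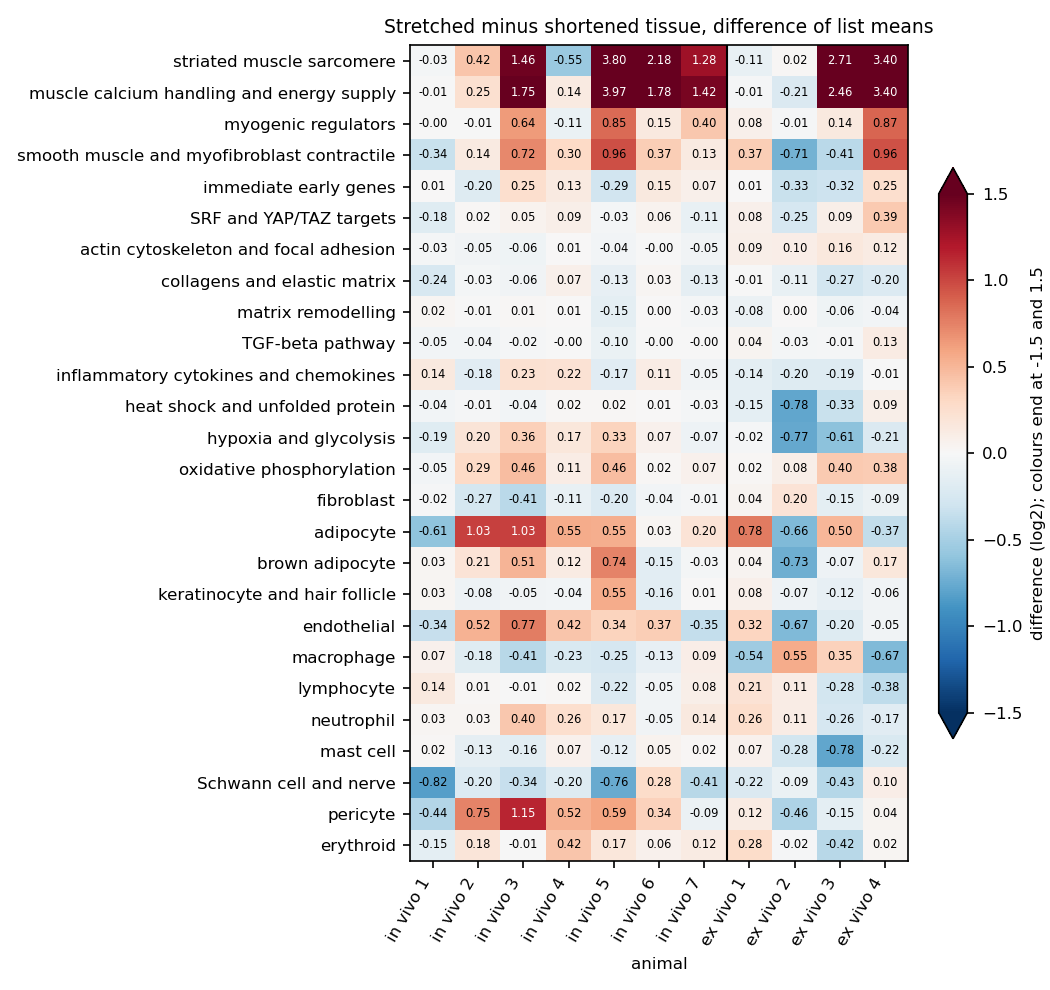
Stretched minus shortened log2 difference of the mean of each of 26 gene lists (vertical) in each of 11 animals (horizontal), with the value in each cell and colours that end at -1.5 and 1.5. The sarcomere list reaches 3.80 in in vivo animal 5 and 3.40 in ex vivo animal 4, and the hypoxia and glycolysis list is below 0 in 4 of 4 ex vivo animals.

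The ex vivo comparison put the same question to tissue held outside the animal. Hypoxia and glycolysis genes, which cells raise when oxygen is short, were lower in stretched tissue in 21 of 23 members and in 4 of 4 animals. Their median was -0.38 and their mean -0.40 ± 0.35 (SD of 4 pairs). The list mean differed by -0.02, -0.77, -0.61 and -0.21 in animals 1 to 4, so animal 1 hardly changed. The list was called with adjusted p = 1.33e-11, against adjusted p = 0.856 with an estimated correlation. None passed over all genes tested and 15 passed adjusted over the list alone. The angiogenic factor Vegfa differed by -0.72 ± 0.15, the oxidase Ero1a by -1.17 ± 0.23, P4ha1 by -0.37 ± 0.08 and the glycolytic enzyme Pgam1 by -0.32 ± 0.05. Outside the list Hilpda, a hypoxia-induced lipid droplet gene, differed by -0.89 ± 0.12.

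Skeletal muscle genes were higher ex vivo on average, by an amount set by 2 of the 4 animals. The sarcomere list had a median of 1.67, with 27 of 31 members higher (adjusted p = 8.23e-07, and adjusted p = 0.856 with an estimated correlation). Its list mean differed by -0.11, 0.02, 2.71 and 3.40 in animals 1 to 4. Shortened tissue ex vivo held a sarcomere mean of 4.80 ± 0.19 (SD, n = 4), and stretched tissue 6.31 ± 1.95 (SD, n = 4). Myh4 differed by 4.07 ± 1.15 and was higher in 4 of 4 animals, Acta1 by 1.91 ± 1.14 in 2 of 4, and titin, Ttn, by 3.07 ± 1.12. The calcium and energy list had a median of 1.63, with 21 of 22 members higher and the list mean in 2 of 4 animals, among them the calcium release channel Ryr1 (2.27 ± 0.77) (adjusted p = 1.45e-06, and adjusted p = 0.856 with an estimated correlation). In neither muscle list did a member pass over all genes or adjusted over the list alone. Without animals 3 and 4 both muscle lists turned direction and lost their calls (adjusted p = 0.0987 for sarcomere and 0.0683 for calcium and energy). The myogenic regulators were not called ex vivo, and Myod1 differed by 0.88 ± 0.46 with adjusted p = 0.530. Animal 4 carried that mean, with Myod1 pair values of 0.20, 0.06, 0.37 and 2.88, and without it Myod1 differed by 0.21.

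Oxidative phosphorylation genes were higher ex vivo as well, in 31 of 31 members and 4 of 4 animals. Their median was 0.21 (adjusted p = 1.66e-09, and adjusted p = 0.856 with an estimated correlation), none passed over all genes, and 4 passed adjusted over the list alone. Examples are Ndufa5 (0.38 ± 0.08), Cox5b (0.26 ± 0.06) and Uqcrc1 (0.44 ± 0.10), subunits of respiratory complexes. This call ended without animals 3 and 4 (adjusted p = 0.766) and with muscle content as a covariate (0.476).

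Heat shock and unfolded protein genes were lower ex vivo in 18 of 22 members and the list mean in 3 of 4 animals, with a median of -0.19 (adjusted p = 0.000232, and adjusted p = 0.856 with an estimated correlation). None passed over all genes, and 1 passed adjusted over the list alone. The chaperone of the endoplasmic reticulum Hspa5 differed by -0.44 ± 0.09, Herpud1 by -0.99 ± 0.27 and Trib3 by -0.81 ± 0.25, all targets of the unfolded protein response. Collagens and elastic matrix genes were lower in 24 of 30 members and 4 of 4 animals, with a median of -0.13 (adjusted p = 0.00155, and adjusted p = 0.856 with an estimated correlation). Among them periostin, Postn, differed by -0.66 ± 0.15, Col6a2 by -0.42 ± 0.12 and P4ha2 by -0.75 ± 0.18, while the crosslinking enzyme gene Loxl1 was higher (0.71 ± 0.20). Col1a1 differed by -0.34 ± 0.12. Mast cell genes were lower in 9 of 10 members and the list mean in 3 of 4 animals, with a median of -0.27 (adjusted p = 0.00490, and adjusted p = 0.856 with an estimated correlation), among them the mast cell proteases Cpa3 (-1.0 ± 0.29) and Mcpt4 (-0.46 ± 0.15). In the collagen and mast cell lists none passed over all genes or adjusted over the list alone. The calls of the lists collagens and elastic matrix and mast cell ended with the muscle covariate in the ex vivo fit (0.0720 and 0.109). At the preset correlation they held with it in the fit of all samples (0.0167 and 0.0445). At an estimated correlation that fit called 0 lists (smallest adjusted p 0.622). Without animals 3 and 4 the collagen and mast cell calls ended as well (0.0761 and 0.0853). The call of heat shock and unfolded protein ended without animal 2 (0.0621). With the muscle covariate its median was -0.46, with 21 of 22 members lower (adjusted p = 6.20e-11, and adjusted p = 0.811 with an estimated correlation), and in the fit of all samples -0.32 (adjusted p = 1.41e-09, and adjusted p = 0.622 with an estimated correlation).

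The other 19 lists were not called ex vivo, with medians from -0.11 to 0.11 and a smallest adjusted p of 0.0643. The muscle covariate gained a call of immediate early genes, with a median of -0.23 and 20 of 29 lower (adjusted p = 0.00136, and adjusted p = 0.811 with an estimated correlation), but not in the fit of all samples (0.0770). Macrophage genes Cd163 (-1.0 ± 0.18) and Csf1r (-0.63 ± 0.12), the prostaglandin synthase Ptgs2 (-0.94 ± 0.17) and the chemokine Cxcl10 (-0.33 ± 0.06) had low p values in lists that were not called. Median, mean and test differed in sign for the smooth muscle (-0.05 and 0.05), matrix remodelling (0.01 and -0.05), brown adipocyte (0.02 and -0.15), neutrophil (0.01 and -0.01) and fibroblast lists, the last with a median of 0.02 and a test direction of lower. Genes with the smallest p were Lyve1 (-1.97 ± 0.20), F13a1 (-0.80 ± 0.11), a coagulation factor subunit made by tissue macrophages, Gnpnat1 (-0.79 ± 0.11) and Tmcc3 (-0.68 ± 0.10) on the lower side. On the higher side they were the adhesion gene Chl1 (0.87 ± 0.11), adenylate kinase Ak1 (0.85 ± 0.13), profilin Pfn1 (0.67 ± 0.12), Pspc1 (0.62 ± 0.10) and the matrix gene Ltbp2 (0.54 ± 0.10). All of these went the same way in 4 of 4 animals, with adjusted p = 0.352.

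In the limma test 0 probes were called ex vivo, and 2508 had an unadjusted p under 0.05, of which 1184 were higher and 1324 lower (958 without animal 3). With all 22 samples in 1 fit, which pools the spread of both settings, 210 probes were called higher and 451 lower. Of the 26 lists camera called 7, fry 0 and exact sign flips 0, where 4 pairs allow no p below 0.125. The Gapdh control difference was 0.19 ± 0.39 for stretched minus shortened tissue ex vivo (SD, n = 4, exact two-sided p = 0.5).

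The stretch effect itself was then compared between settings, as in vivo minus ex vivo. Limma called 24 genes higher and 10 lower for this difference. Among them Vegfa, Hilpda, Higd1a and Fam162a are linked to low oxygen, a grouping made after the calls were seen and not tested. Each was lower after stretch in 4 of 4 ex vivo animals and not called in vivo (adjusted p from 0.172 to 0.594) or ex vivo (0.352). Only Vegfa of these belongs to the hypoxia and glycolysis list. Vegfa differed by 0.25 ± 0.07 in vivo and -0.72 ± 0.15 ex vivo, a difference of 0.96 ± 0.16 (adjusted p = 0.0464). The hypoxia-induced genes Hilpda (0.98 ± 0.14, adjusted p = 0.0455), Higd1a (0.86 ± 0.14, adjusted p = 0.0464) and Fam162a (0.67 ± 0.11, adjusted p = 0.0464) followed the same course. Of the called genes Lyve1 had the largest difference, 1.70 ± 0.19 (adjusted p = 0.0140), with -0.28 in vivo and -1.97 ex vivo. Zic1, named after its values were seen, had a larger one that was not called (-3.13 ± 0.58, adjusted p = 0.0533). Of the genes with a lower effect in vivo, the interferon-induced Ifitm1 (-1.01 ± 0.17) was lower in vivo (-0.34) and higher ex vivo (0.67), and Chl1 differed by -1.0 ± 0.17 and the endothelial receptor Adgra2 by -0.99 ± 0.17 (each adjusted p = 0.0464).

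Of 26 lists 7 were called for this difference. Hypoxia and glycolysis differed by a median of 0.49, with 21 of 23 members higher (adjusted p = 3.08e-11, and adjusted p = 0.371 with an estimated correlation). Of its members 1 passed over all genes, Vegfa, and 15 adjusted over the list alone. Heat shock genes differed by 0.17 (19 of 22 higher, 0 over all genes, 4 adjusted over the list alone, adjusted p = 0.000133, and adjusted p = 0.761 with an estimated correlation). Pericyte genes differed by 0.52 (7 of 7 higher, adjusted p = 0.00695, and adjusted p = 0.761 with an estimated correlation) and adipocyte genes by 0.41 (13 of 16 higher, adjusted p = 0.0408, and adjusted p = 0.761 with an estimated correlation), in both with no member passing over all genes or adjusted over the list alone. Endothelial genes differed by 0.39 (14 of 17 higher, adjusted p = 0.0111, and adjusted p = 0.761 with an estimated correlation), where Lyve1 passed over all genes and adjusted over the list alone. Mast cell genes differed by 0.25 (8 of 10 higher, adjusted p = 0.0307, and adjusted p = 0.761 with an estimated correlation), with 0 members over all genes and 1 adjusted over the list alone. Actin and focal adhesion genes, which link the cytoskeleton to matrix, differed by -0.12 (18 of 25 lower, adjusted p = 0.00695, and adjusted p = 0.371 with an estimated correlation). Of these 0 passed over all genes and 4 adjusted over the list alone, 3 lower and 1 higher. The sarcomere list was not called (-0.25, adjusted p = 0.664). Nor was the calcium and energy list, whose median of -0.22 and mean of -0.08 differed in sign from its test direction (adjusted p = 0.838).

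Over all probes limma called 40, 29 higher and 11 lower, with 3460 at an unadjusted p under 0.05. The count ran from 0 without in vivo animal 2 or ex vivo animal 3 to 663 without ex vivo animal 1, with 331 without ex vivo animal 4 and 9 without the 4 muscle-rich pairs, and it was 1 and 0 within the low and high Gapdh sets. Calls of the lists actin cytoskeleton and focal adhesion (adjusted p = 0.0709) and mast cell (0.231) ended without the 4 muscle-rich pairs, that of mast cell also in the low Gapdh set (0.171) and that of adipocytes without the animal block (0.241). Across 12393 genes, which are not independent replicates, the in vivo and ex vivo effects had Pearson r = 0.428 and Spearman rho = 0.124. Exact flips of the ex vivo pairs, two-sided, gave p = 0.375 and p = 0.63, with 0.125 the smallest possible from 16 flips. The sign was shared by 53.0% of genes, and r was 0.257 without the 2 skeletal muscle lists.

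Shortened tissue was compared between settings, 4 ex vivo against 7 in vivo samples from different animals, to describe the state in which stretch acted. Setting and batch cannot be told apart here, and the distributions looked normalized separately, with a median shift of -0.38 over all probes. Changes are therefore given relative to that shift. Calls of probes and list members, and their counts as higher or lower, come from uncorrected values tested against no change. The Gapdh control of RNA quality differed as well. Its difference between 3' and 5' probes was 1.61 ± 1.38 in shortened tissue in vivo (SD, n = 7) and 0.13 ± 0.05 ex vivo (SD, n = 4). The Actb control was closer, at 1.02 ± 0.64 in vivo (SD, n = 7) and 0.83 ± 0.10 ex vivo (SD, n = 4). Inflammatory genes were far higher ex vivo. The neutrophil chemokine Cxcl5 rose by 9.54 ± 0.10, with mean signals of 2.89 in vivo and 12.05 ex vivo before that correction. Its in vivo signal lay below the lower quartile of the in vivo samples (5.08 to 5.22), near the floor of the array, so the size of the change is uncertain. The cytokine Il6 rose by 7.24 ± 0.37, the chemokines Cxcl1 by 7.03 ± 0.41 and Cxcl2 by 6.58 ± 0.40, and the iron-binding protein gene Lcn2 by 6.62 ± 0.17. The protease inhibitor Serpinb2 (8.66 ± 0.19), the pattern recognition gene Ptx3 (7.20 ± 0.11), the itaconate enzyme Acod1 (6.97 ± 0.20), the cholesterol hydroxylase Ch25h (6.87 ± 0.13) and the AP-1 subunit Fosl1 (6.46 ± 0.12) complete the 10 largest measured rises. Serpinb2, Acod1, Ch25h, Lcn2 and Fosl1 also lay below that quartile in vivo (2.30 to 4.96), so the sizes of their changes are uncertain as well and the order of the 10 is not settled. All 29 members of the inflammatory list were higher than the shift, with a relative median of 2.75, and 28 passed both over all genes and adjusted over the list alone (adjusted p = 1.51e-24, and adjusted p = 0.0392 with an estimated correlation).

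Stress lists were higher ex vivo too. Heat shock and unfolded protein genes had a relative median of 1.32, with 18 called over all genes and adjusted over the list alone, 17 of them higher (adjusted p = 5.63e-12, and adjusted p = 0.134 with an estimated correlation). The inducible chaperones Hspa1a and Hspa1b rose by 3.62 and 3.53, and the haem oxygenase Hmox1 by 3.79. Hypoxia and glycolysis genes had a relative median of 1.25, with 20 called both ways of adjusting and 18 of these higher (adjusted p = 1.83e-12, and adjusted p = 0.134 with an estimated correlation). The lactate transporter Slc16a3 rose by 5.66, the oxygen sensor Egln3 by 5.33, the glucose transporter Slc2a1 by 3.89 and Ero1a by 3.79. Matrix remodelling genes had a relative median of 0.94 (adjusted p = 0.000101, and adjusted p = 0.143 with an estimated correlation). Of these 22 passed over all genes and 24 adjusted over the list alone, 14 higher and 10 lower. Timp1 rose by 3.41 and Mmp12 by 3.24, and Timp3 fell by 1.94. Actin and focal adhesion genes had a relative median of 0.41, with 19 called over all genes and adjusted over the list alone, 10 higher and 9 lower (adjusted p = 0.0189, and adjusted p = 0.143 with an estimated correlation). Immediate early genes had a relative median of 0.35 where the median without that correction was -0.03 and the mean 0.34 (adjusted p = 0.00427, and adjusted p = 0.662 with an estimated correlation). Over all genes 23 of them were called and adjusted over the list alone 25, with Gadd45b (4.62) and Maff (3.75) higher and Klf2 (-3.35) lower.

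Macrophage genes were the lowest list ex vivo, with a relative median of -2.70 and 17 of 18 members called lower both over all genes and adjusted over the list alone (adjusted p = 0.000101, and adjusted p = 0.662 with an estimated correlation). They include the scavenger receptor Cd163 (-4.69), the lectins Mgl2 (-3.94) and Mrc1 (-3.82) and the CSF1 receptor gene Csf1r (-2.78). Other genes of tissue macrophages were among the largest falls, Cd209g (-4.94 ± 0.10), Cd209f (-4.89 ± 0.08), Fcrls (-4.73 ± 0.08) and P2ry12 (-5.0 ± 0.17). Thrsp (-5.53 ± 0.51) and Pck1 (-5.04 ± 0.64), genes of fat metabolism, were there as well, with the prostaglandin receptor Ptger3 (-5.29 ± 0.42), the protocadherin Pcdh20 (-5.22 ± 0.18) and the methyltransferase Inmt (-4.76 ± 0.29). Ptger3 (3.65), Pck1 (4.43) and P2ry12 (3.31) lay below the lower quartile of the ex vivo samples (4.68 to 4.81), so the sizes of their falls are uncertain too. Oxidative phosphorylation genes had a relative median of -0.53, with 28 of 31 called lower over all genes and adjusted over the list alone (adjusted p = 0.00376, and adjusted p = 0.870 with an estimated correlation), among them Cox6c (-1.13) and Sdhd (-1.19).

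Of the 26 lists 18 were not called, with relative medians from -2.03 for adipocytes to 0.40. Their relative median and test direction differed in sign for sarcomere (-1.21), calcium and energy (-1.45), smooth muscle (-0.30), TGF-beta (-0.24), keratinocyte (-0.05) and pericyte genes (-0.31), each with an upward test direction. By limma 16550 of 22626 probes were called, 73.1%, of which 3943 were higher and 12607 lower, and 16391 and 17522 within the low and high Gapdh sets of in vivo animals. After quantile normalization of the 11 samples 7404 were higher and 7790 lower. Quantile normalization of all 22 samples ended the call of immediate early genes (adjusted p = 0.107) and the low Gapdh set that of actin genes (0.0698). With these settings and the high Gapdh set, 0 lists were called with an estimated correlation, the inflammatory cytokines and chemokines included (0.208, 0.376 and 0.211). Fry, which tests uncorrected values against no change and so takes in the median shift, called 24 lists and gave the actin genes a downward direction (0.297).

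**Figure D3:**
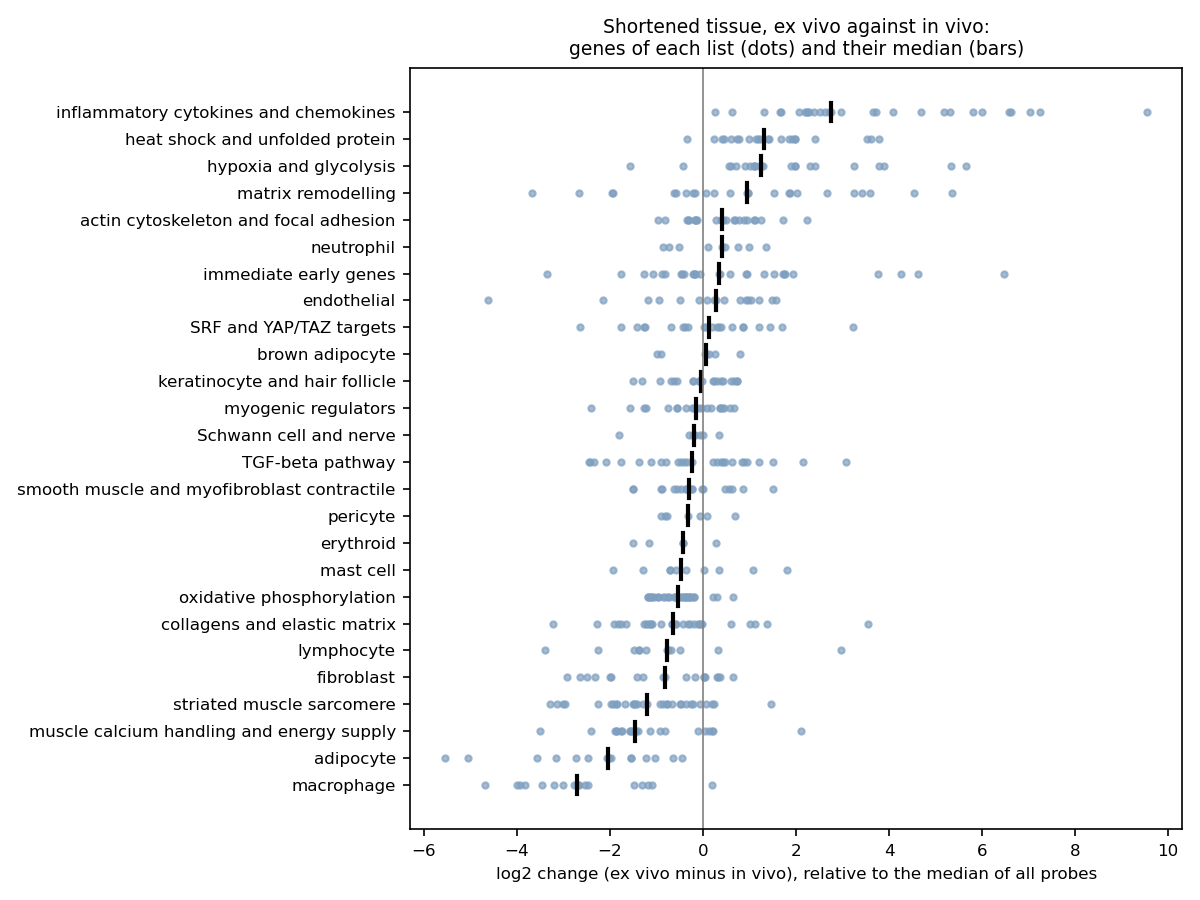
Log2 change of shortened tissue, ex vivo minus in vivo, relative to the median of all probes, for the genes (dots) and the median (bars) of each of 26 lists. The inflammatory list is highest at 2.75 and the macrophage list lowest at -2.70.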

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

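The tests chosen only after the result was seen were the range of muscle content without stretch, the sign flips of the sarcomere and hypoxia lists, and the covariates of muscle content and RNA quality.

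Muscle transcripts were higher in stretched tissue, and the sarcomere mean differed between the pieces of an animal by -0.55 to 3.80 in vivo. Skeletal muscle in the pieces may be a source: across the 53 genes of the muscle lists, which are not independent replicates, the slope on muscle content in shortened in vivo tissue ranked the genes as the stretch difference did (Spearman rho 0.843 in vivo and 0.867 ex vivo), and 35 of 37 genes with a slope above 0.5 were higher in stretched tissue in vivo. Muscle content varied without stretch as well, by 4.42 between shortened in vivo samples, where Acta1 averaged 9.07 ± 3.29 (SD, n = 7), against at most 3.80 within an animal, but not ex vivo, where shortened samples spanned only 4.68 to 5.08 and pairs differed by up to 3.40. A stretch response of the connective tissue stays open. The exact two-sided sign-flip p of the sarcomere mean was 0.0938 over 7 pairs. It asks only whether stretched pieces held more sarcomere signal, whatever its source, so it cannot decide between the causes. A muscle programme induced in full could give the same profile, so the rank test does not separate it from admixed panniculus carnosus.

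In vivo 4373 probes had an unadjusted p under 0.05, where 1131.3 are expected, though limma called 0 after adjustment. The Gapdh difference as a covariate did not lower that count, with 4596 probes at an unadjusted p under 0.05. Of 100 assignments of its values to the wrong animals 71 gave counts as low (3238 to 6307). This test thus cannot settle RNA quality as a cause, and it stays open. Muscle content and fat content of the pieces may each contribute, with 1097 and 1722 probes as covariates, but 18 and 16 of 100 wrong assignments gave counts as low (medians 2322 and 2657.5), which keeps both open beside a stretch response. Among swaps within animals 3 of 64, the real one included, gave as many as the real 4373 (highest other 5048, from swapping animal 1 alone). That share lies only just under 0.05, so chance is unlikely but not excluded. Of 100 drawn splits of the 14 samples 4 gave as many (highest other 6567, which parted 3 pairs), but the real split parts all 7 pairs and only 6 other drawn ones do, so these splits are no like reference and add nothing to the swaps.

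Hypoxia and glycolysis genes were lower in stretched tissue ex vivo, with a median of -0.38. Dilution by muscle RNA is argued against by the median, which was -0.39 with muscle content as a covariate in the fit of all samples. The list was still called in that fit at the preset correlation (adjusted p = 9.83e-14). With an estimated correlation that fit called 0 lists (smallest adjusted p 0.622). A stretch response of the explant is possibly the cause and stays open, since the exact two-sided sign-flip p of 0.125 is the smallest that 4 pairs allow. Oxygen supply to the explants was not tested, and setting and batch cannot be told apart for the contrast with the in vivo tissue.

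Of 100 drawn splits of the animals 1 gave as many called probes for the difference of the stretch effect, the real one (40 probes, highest other 7). Chance is thus unlikely but not excluded, and the count hung on single animals. It was 0 without in vivo animal 2 or ex vivo animal 3 and 663 without ex vivo animal 1. In the comparison of shortened tissue between settings again 1 of 100 gave as many (16550 probes, highest other 0). Sample medians of the settings did not overlap (6.85 to 6.90 ex vivo, 7.29 to 7.42 in vivo). Every other split mixes the settings and so puts their difference into the spread. Such splits are no like reference, and they cannot tell setting from batch or separate normalization. For the ex vivo stretch effect 1 of 8 swaps gave as many (2508 probes, highest other 2368), and 8 swaps are too few for a share under 0.05.

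Single samples stood far from the others of their group in 19 of 156 groups of list means, where chance gives about 1 in 20, or 7.8. In vivo animal 1 stood low in the adipocyte list, at 9.63 shortened (others 11.13 to 12.12) and 9.03 stretched (others 12.06 to 12.50). Its stretched sample was also low in the pericyte list at 6.79 (others 8.16 to 8.96), in hypoxia and glycolysis at 9.17 (9.74 to 10.06) and in oxidative phosphorylation at 10.98 (11.46 to 11.77). In vivo animal 5 stood high in keratinocyte genes, at 5.61 stretched (4.87 to 5.15) and 0.55 in its difference (-0.16 to 0.03), and low in matrix remodelling, at 7.99 stretched (8.13 to 8.19) and -0.15 in its difference (-0.03 to 0.02). Shortened in vivo samples stood apart for animal 4 in myogenic regulators at 6.34 (5.64 to 5.87) and for animal 6 in SRF and YAP/TAZ targets at 9.05 (9.17 to 9.25). Ex vivo animal 4 stood apart in the sarcomere list at 5.08 shortened (4.68 to 4.74), and stretched in myogenic regulators at 6.11 (5.17 to 5.30), the TGF-beta pathway at 8.24 (8.16 to 8.17) and neutrophil genes at 4.95 (5.33 to 5.38). Ex vivo animal 3 stood apart in its stretched sample in matrix remodelling at 8.80 (8.51 to 8.54) and erythroid genes at 3.97 (4.26 to 4.29). Ex vivo animal 2 did so shortened in collagens at 10.21 (10.08 to 10.10) and brown adipocyte genes at 4.91 (4.01 to 4.16).

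The stretch effect differed between settings, as in vivo minus ex vivo, for 7 lists by camera, all lost with an estimated correlation. Their medians were 0.52 for pericyte, 0.49 for hypoxia and glycolysis, 0.41 for adipocyte, 0.39 for endothelial, 0.25 for mast cell, 0.17 for heat shock and -0.12 for actin and focal adhesion genes. Among genes called by limma the difference was higher for Lyve1 (1.70), Sult1a1 (1.06), Srgap1 (1.02), Hilpda (0.98), Vegfa (0.96), Higd1a (0.86), Tmcc3 (0.81), Peak1 (0.77), F13a1 (0.71) and Fam162a (0.67). It was lower for Ifitm1 (-1.01), Chl1 (-1.0), Adgra2 (-0.99), Pspc1 (-0.65), Slc6a6 (-0.61), Ssbp3 (-0.47) and Arl2bp (-0.47).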

How the results depend on the processing

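Chosen only after the result was seen were the settings with muscle content as a covariate, without the muscle-rich pairs, with sign flips of list means, within the Gapdh sets, with quantile normalization of all 22 samples, and each of these fits with an estimated correlation. Limma called 0 probes in vivo under every setting tried, with unadjusted counts from 1080 to 5540, and the smallest adjusted p was 0.0661. The number of arrays limits the precision. The list calls of the stretch comparisons depend on the preset correlation of camera, since none held with an estimated correlation, and muscle content, the animal block and single animals moved calls and counts as well. Where a value below moved, the cause was not tested, except that settings with fewer probes, genes or animals test fewer of them, and that the muscle covariate is made of the muscle lists themselves.

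Ex vivo 0 probes were called by limma with 2508 at an unadjusted p under 0.05, and 210 were called higher and 451 lower with all samples in 1 fit. For the difference of the stretch effect, 29 higher and 11 lower, quantile normalization gave 5 and 0, brighter probes 78 and 50, probes with a mean of at least 6 gave 51 and 23, no mean-variance trend 4 and 0, array weights 198 and 132, a threshold of 0.10 gave 178 and 166, and no animal block 3 and 0. Median centring gave 4 lower, the brightest probe of a gene 17 lower and the muscle covariate 18 lower. The low Gapdh set gave 1 and 0, the high set 0 and 0, and leaving out the 4 muscle-rich pairs 7 and 2. Leaving out 1 animal gave 0 to 343 higher and 0 to 320 lower.

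For shortened tissue between settings, 3943 higher and 12607 lower, quantile normalization gave 7404 and 7790, the same on all 22 samples 7405 and 7795, median centring 8352 and 6690, brighter probes 2112 and 6724, the mean of the probes of a gene 1933 and 7418, and the brightest probe 1958 and 7636. Probes with a mean of at least 6 gave 8367 lower, and a change of at least 1.5-fold gave 2486 higher.

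In vivo an estimated correlation called 0 lists, with adjusted p = 0.446 for sarcomere, calcium and energy, and oxidative phosphorylation genes. Fry called 0, with 0.277, 0.184 and 0.184 for the same lists, and exact sign flips called 0, with 0.244, 0.232 and 0.232. The muscle covariate gave 0.942 for sarcomere and 0.942 for myogenic genes, both with a turned test direction, and 0.186 for calcium and energy. The myogenic median stayed positive with it, at 0.02. Ex vivo an estimated correlation called 0 lists, with adjusted p = 0.856 for sarcomere, calcium and energy, hypoxia, and oxidative phosphorylation genes. Fry called 0, with 0.758, 0.758, 0.480 and 0.522, and exact sign flips 0, with 0.855, 0.855, 0.650 and 0.650. The muscle covariate called 3 lists ex vivo, hypoxia, heat shock and immediate early genes, the last a gained call (0.00136), with 0.754 for sarcomere and 0.496 for calcium and energy, both turned, and 0.476 for oxidative phosphorylation. Without the 2 muscle-rich pairs 3 lists were called, with 0.0987 and 0.0683 for the muscle lists, both turned, and 0.766 for oxidative phosphorylation. Leaving out 1 animal ex vivo gave 8 to 11 lists. For the difference an estimated correlation called 0 lists (hypoxia 0.371), fry 1, actin cytoskeleton and focal adhesion (0.00656, with hypoxia at 0.0726), and the fit without the 4 muscle-rich pairs 12. Between settings an estimated correlation called 1 list and fry 24, with actin genes at 0.297 and turned, on uncorrected values tested against no change. The muscle covariate, the fits without the muscle-rich pairs, the Gapdh sets and quantile normalization of all 22 samples each called 0 lists with an estimated correlation.

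Single genes that turned with the mean of their probes were Dio2 in vivo (0.11) and between settings (1.07), Epb42 (-0.033) and Slc4a1 (0.024) ex vivo, and Epb42 for the difference (0.035). Quantile normalization turned Dio2 (0.023) and Slc27a2 (0.048) between settings. Leaving out 1 animal turned genes near 0, with ranges in vivo of -0.091 to 0.0099 for Cpa3, -0.056 to 0.043 for Hba-a1 and -0.14 to 0.0023 for Tgfb1. The ranges ex vivo were -0.034 to 0.67 for Dgat2, -1.17 to 0.0060 for Thrsp, -0.27 to 0.44 for Ppargc1a, -0.20 to 0.023 for S100a9, -0.20 to 0.010 for Ngp, -0.26 to 0.080 for Camp, -0.43 to 0.015 for Rgs5, -0.28 to 0.021 for Hbb-b2, -0.35 to 0.19 for Alas2, -0.053 to 0.011 for Slc4a1 and -0.88 to 0.13 for Acta2.

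Of other called lists, 101 of 144 values in vivo kept direction and call, 42 lost the call and 1 turned. Ex vivo 19 of 33 kept both and 14 lost the call, for the difference 33 of 48 and 15, and between settings 32 of 42 and 9, with 1 turned. Named genes kept direction and side of the threshold in 1146 of 1150 values in vivo, 798 of 812 ex vivo, 1453 of 1666 for the difference (171 lost and 41 gained a call) and 1519 of 1534 between settings. In vivo and ex vivo no gene was called in any setting used for named genes. There the counts show only whether the direction held.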

Other observations

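The position-gene count was the test chosen only after the result was seen. Several groups that were not called as lists between settings held large single changes in shortened tissue, given ex vivo minus in vivo relative to the median shift. Collagen and elastic matrix genes had a relative median of -0.64 (adjusted p of the list 0.118). On uncorrected values 29 of 30 passed adjusted over the list alone, 4 of them higher. Col5a1 changed by -3.22, Col6a2 by -2.27 and Col6a1 by -1.76. Fibroblast markers had a relative median of -0.81 (adjusted p of the list 0.0840), with Dpp4 at -2.64, Fap at -2.00 and Dpt, a matrix protein gene of dermal fibroblasts, at -1.28. Quantile normalization of all 22 samples called the lists collagens and elastic matrix (0.00867), fibroblast (0.0225), adipocyte (0.0120) and lymphocyte genes (0.0225) lower, and with an estimated correlation none of these (0.244, 0.599, 0.836 and 0.276). The immunoglobulin gene Ighm changed by -3.39 and Cd2 by -2.26, while the IL-7 receptor gene Il7r rose by 2.96. In the TGF-beta pathway the repressor Tgif1 rose by 3.07, and the ligand Bmp4 changed by -2.46 and Tgfbi by -2.43. Lyve1, which differed most in its stretch effect among called genes, changed by -4.62 between settings, and the endothelial receptor Tek by -2.15.

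Load-sensitive genes gave single values ex vivo in lists that were not called. Ankrd1, a YAP target abundant in muscle, differed by 1.89 ± 0.73 in stretched tissue (SE, n = 4), Flnc, a muscle filamin, by 0.93 ± 0.31, and Ccn1, another YAP target, by -0.65 ± 0.18. Timp1, an inhibitor of matrix proteases, differed by 0.48 ± 0.09.

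Zic1 and Pax1, transcription factors tied to body position, were among the lowest p in vivo. The stretched and shortened pieces may thus have come from different positions along the trunk, though pieces were assigned at random. Ex vivo Zic1 differed by -0.34, 3.02, 0.68 and 1.33 in animals 1 to 4, so most pairs went the other way. A list of 46 other position genes was written for this test, without Zic1 and Pax1, which led to it. Of these 12 had an unadjusted p under 0.05, against a median of 7 in 10000 random lists matched on expression. A share of 0.0578 of the random lists held as many, so the question stays open. Tbx3 (0.71 ± 0.14, SE, n = 7), Hoxa3 (-0.30 ± 0.06), Zic4 (-0.28 ± 0.08), Hoxa9 (-0.29 ± 0.09) and Hoxb6 (0.35 ± 0.11) had the lowest p among them.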
